A study of Mus musculus with 6 samples.

How the data were processed

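RNA from frozen mouse hearts was sequenced in 6 libraries, 3 from hearts given AAV9-EGFP and 3 from hearts given AAV9 anti-miR-199a tough decoys (TuDs), prepared from total RNA with an NEBNext Ultra RNA kit per the labels. Samples were grouped by the labels alone. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to mm10 and counted with featureCounts 1.5.0-p3; the annotation release and the strand setting are not stated. The deposited values are FPKM for 54532 genes, with each gene's length. FPKM times gene length came out as whole reads, within 0.05 of a read, for 100% of the values above 0 in each library, which gave 15.2 to 18.2 M reads (M, megareads) per library. The library sizes the authors divided by were 0.943 to 1.06 of these totals.

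Of the 54532 gene identifiers, 54409 are in GENCODE release M21 (GRCm38), 53499 of them with the same coordinates and 53815 with the same symbol. That annotation supplied the 3' UTRs of 20980 genes and the transcript GC content.

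FPKM columns were divided by median-of-ratios size factors (0.985 to 1.02) and are called normalised FPKM. Genes with a deposited FPKM of at least 1 in at least 3 of the 6 samples were tested, 10460 in all. The comparison was a 2-group limma model (lmFit and eBayes with a mean-variance trend) on log2 of the normalised FPKM plus 0.5, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are TuD minus control. A model for counts was not the main test because the deposited values are FPKM.

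Gene lists were fixed before the data were examined, 32 in all, and 24 of them had at least 5 tested members. These were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists. Camera with an estimated correlation passed none of the 24 (smallest adjusted p = 0.836), and fry, which asks only whether a list's genes move one way on balance, passed 3 (ribosomal proteins, oxidative phosphorylation and adipocyte markers). The 8 lists with fewer tested members were given as values. For Ppargc1a an exact permutation test was added.

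Named genes followed a rule written before the data were examined. It took the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among genes past the threshold with a mean of at least 1 and groups that did not overlap, up to 4 tested members of each list by p-value, and 11 genes of prior interest. Igkc, Fos and Egr1 fall outside it and were chosen after their values were seen, as were the list members named only as not passing.

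For the seed comparison, sites of 7 or 8 bases matching miR-199a-5p or miR-199a-3p were searched in the longest annotated 3' UTR, and genes without an annotated 3' UTR were left out. Alternatives planned before the data were examined were 3 other scalings, 2 pseudocounts, 2 filters, 2 variance models, limma-voom on the recovered reads, the replicate number as a block, other thresholds, other site definitions, matched genes, and leaving out each library. After the data were seen, corrections for gene length and for length and GC content (lowess with a span of 0.3), protein-coding genes only, and a covariate for the presence of Y-linked transcripts were added.

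The pipeline was tested on simulated data of the same size with 200 genes changed singly, a further gene set raised together and the same dispersion for every gene. It recovered 91.7% of genes changed 2-fold, 40.8% of those changed 1.5-fold and 4.08% of those changed 1.25-fold, with 7.03% of calls false. With a length trend added between the groups 63.3% of calls were false, and 11.1% after the length correction. The simulated trend was stronger than that of the data (correlation of log2 fold change with log10 length -0.612 against -0.386). These shares of false calls follow from the settings of the simulation and do not carry over to the real comparison. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.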

Results

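RNA was sequenced from the myocardium of 6 hypertrophic mouse hearts in 2 groups. The 3 controls had received adeno-associated virus of serotype AAV9 carrying EGFP, and the other 3 had received AAV9 carrying anti-miR-199a tough decoys (TuDs), hairpin RNAs that bind a microRNA and keep it from its targets. The mice were wild-type C57BL/6 animals of 18 weeks. The labels do not state the sex of the animals, how hypertrophy was induced, the dose of virus, the hour of collection or whether each sample is a separate animal. Every p-value therefore measures the spread between samples. Reads recovered from the deposited FPKM came to 18.1 ± 0.115 M (megareads) in the controls (SD, n = 3) and 16.0 ± 0.731 M in the TuD group (SD, n = 3), with a range over the libraries of 15.2 to 18.2 M. At these depths, 3 reads over a transcript of 2 kilobases equal an FPKM of 0.0774 to 0.104.

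Transcripts of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) separated the libraries in a way the labels do not describe. Their summed FPKM was 9.59, 8.32 and 8.97 in control replicates 1, 2 and 3 and 12.5 in TuD replicate 3, but 0.0254 in TuD replicate 1 and 0.00711 in TuD replicate 2. Xist, the RNA that coats the inactive X chromosome, had no reads in the controls and reached 1.43, 0.127 and 0.0167 normalised FPKM in TuD replicates 1, 2 and 3. The 2 TuD libraries without Y-linked transcripts have no counterpart among the controls. A model with this difference as a covariate, chosen after seeing the data, rests its estimate of the treatment on TuD replicate 3 alone. A call that ended with this covariate can therefore reflect lost precision and does not show that sex explains the difference. Among the named genes whose call ended in this way most estimates shrank. Those of the complement gene C7 (-2.14 to -0.64), Xirp2 (+0.99 to +0.42) and Mfap5 (+0.88 to +0.35) are examples. A minority grew, such as that of the globin gene Hba-a2 (+1.09 to +1.36), and all of these estimates rest on TuD replicate 3.

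The comparison asked which transcripts differ between hypertrophic hearts with and without the decoys. Gpam, Ppara and Slc8a1 had log2 fold changes among the 10 lowest. Gpam, the mitochondrial acyltransferase that starts glycerolipid synthesis (ENSMUSG00000024978, chromosome 19, 55069734 to 55099451 in mm10), fell from 28.2 ± 6.37 to 3.76 ± 0.766 normalised FPKM (SD, n = 3 per group). Ppara, the nuclear receptor that drives fatty acid oxidation genes (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819), fell from 8.32 ± 1.88 to 1.22 ± 0.758. Slc8a1, the sodium-calcium exchanger (ENSMUSG00000054640, chromosome 17, 81388691 to 81649607), fell from 31.7 ± 7.72 to 6.72 ± 2.82. Their log2 fold changes were -2.74 ± 0.20 (SE, adjusted p = 0.00149), -2.42 ± 0.29 (adjusted p = 0.00241) and -2.20 ± 0.28 (adjusted p = 0.00257). For each gene all 3 TuD values lay below all 3 control values, which the rule for naming these genes required.

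Among the 10 lowest log2 fold changes were also Nt5c1a, a cytosolic nucleotidase (-2.87), Pdpr, a regulator of pyruvate dehydrogenase phosphatase (-2.41), Nr4a1, an immediate early nuclear receptor (-2.26), Pm20d2 (-2.17), C7, a complement component (-2.14), and Scn4b, a sodium channel subunit (-2.05). The 10 highest were mt-Atp6 (+2.85), Cfd, which is complement factor D (+2.72), mt-Nd3 (+2.48), mt-Co3 (+2.38), Polr2k, a subunit shared by the nuclear RNA polymerases (+1.98), Igip (+1.98), Rpl21 (+1.70), Snrpe, a core protein of the spliceosome (+1.68), Rps27a (+1.68) and Gm34302 (+1.63). Polr2k rose from 7.56 ± 1.58 to 31.3 ± 6.28 normalised FPKM (adjusted p = 0.00184). Cfd rested on 19 control reads and 232 TuD reads. With the Y-linked covariate the calls ended of Nr4a1 (adjusted p = 0.0548), C7 (-0.64, 0.105), mt-Nd3 (+1.09, 0.281), mt-Co3 (+1.56, 0.196) and Snrpe (+1.33, 0.144). The length correction ended that of mt-Nd3 (+1.86, 0.0681), the length and GC correction those of mt-Nd3 (+1.17, 0.252), mt-Co3 (+1.52, 0.0963) and Snrpe (0.0775), and quantile normalization that of mt-Co3 (0.0555). Robust eBayes ended those of mt-Nd3 (0.0785), mt-Co3 (0.0598) and C7 (0.0653). C7 measured 0.661, 0.724 and 5.17 normalised FPKM in TuD replicates 1, 2 and 3. Leaving out a single library ended the calls of mt-Nd3 (adjusted p = 0.0650 without control replicate 3, 0.0736 without TuD replicate 1, 0.0783 without TuD replicate 2) and mt-Co3 (0.0591 without TuD replicate 1, 0.0657 without TuD replicate 2). The same held for C7 (0.0522 to 0.0760 without control replicate 2 or 3 or TuD replicate 1 or 2) and Snrpe (0.0534 to 0.0631 without control replicate 2 or 3 or TuD replicate 2).

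Of 10460 genes tested, 1565 genes were higher and 1498 genes were lower in the TuD group at an adjusted p under 0.05, which is 29.3% of the tested genes, and 228 and 153 of them changed at least 2-fold. The groups did not overlap for 5012 genes (47.9%), where the average over all splits of 6 samples is 10%. Genes move together, as they did with gene length, so a single split can lie far from that average and the comparison is not a test. Among protein-coding genes 1291 were higher and 1428 lower, and among 445 processed pseudogenes 154 were higher and 26 lower. The balance between the directions depended on the scaling: rescaling to TPM moved the median of all tested genes to -0.36 on the log2 scale and gave 438 higher and 4202 lower genes. Each change here is therefore relative to the median gene. Leaving out control replicate 1, 2 or 3 or TuD replicate 1 left 979, 718, 838 and 996 lower genes, leaving out control replicate 2 or 3 left 878 and 960 higher genes, and the Y-linked covariate left 651 higher and 529 lower genes. Among the genes this report names by its rule, the calls that ended without a filter were those of mt-Nd1 (adjusted p = 0.306), mt-Nd3 (0.0952), mt-Co3 (0.0842), C7 (0.0885), Snrpe (0.0706), Atp2a2 (0.121), Myh7 (0.110), Xirp2 (0.0845), Mfap5 (0.0745), Lum (0.0921), Dkk3 (0.143), Hba-a1 (0.149), Hba-a2 (0.0773), Pcna (0.0869) and Dusp1 (0.0594).

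Transcripts for cytosolic ribosomal proteins were higher in the TuD hearts almost throughout. Of 46 tested members, 44 rose, none fell and 2 did not pass the test, and all 46 rose when adjusted over the list alone. Rpl23 rose from 49.7 ± 3.95 to 133 ± 11.6 normalised FPKM (log2 fold change +1.40 ± 0.11 SE, adjusted p = 0.00149), Rpl30 from 19.4 ± 1.52 to 59.3 ± 10.9 and Rps24 from 25.6 ± 1.44 to 55.5 ± 2.18 (SD, n = 3 per group). The list had a median log2 fold change of +0.80 (camera adjusted p = 3.8e-21; adjusted p = 0.836 with an estimated correlation). Ribosomal proteins have many processed pseudogenes that can share their reads.

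Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were also higher. Of 77 members 58 rose, none fell and 19 did not pass, and 59 rose when adjusted over the list alone. Cox6c rose from 128 ± 13.6 to 345 ± 51.5 normalised FPKM (+1.42 ± 0.14 SE, adjusted p = 0.00194) and Cox7a2 from 280 ± 19.3 to 711 ± 122 (+1.33 ± 0.14 SE, adjusted p = 0.00197), both subunits of cytochrome c oxidase. Ndufa6 of complex I had a log2 fold change of +1.08 and Atp5l of ATP synthase one of +1.11. The list's median was +0.69 (camera adjusted p = 1.2e-17; adjusted p = 0.836 with an estimated correlation), and +0.26 with quantile normalization (adjusted p = 5.9e-06).

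Of the 13 mitochondrially encoded genes 6 rose (7 when adjusted over the list alone), none fell and 7 did not pass, with a median log2 fold change of +1.10 (camera adjusted p = 0.00455; adjusted p = 0.862 with an estimated correlation). mt-Atp6, the ATP synthase subunit encoded on the mitochondrial genome (ENSMUSG00000064357, chromosome MT, 7927 to 8607), rose from 309 ± 205 to 1940.4 ± 433 normalised FPKM (+2.85 ± 0.44 SE, adjusted p = 0.00451). The complex I gene mt-Nd1 rose from 12526 ± 4484 to 26086 ± 5053 (+1.10, adjusted p = 0.0265). That call ended without control replicate 2 (adjusted p = 0.102), control replicate 3 (0.0779), TuD replicate 1 (0.0762) or TuD replicate 2 (0.0629) and with the Y-linked covariate (0.211). It ended as well after the length correction (+0.70, 0.103), the length and GC correction (+0.23, 0.543) and quantile normalization (+0.32, 0.151). Mitochondrial genes took 8.52 ± 3.33% of the reads in the controls and 13.7 ± 3.33% in the TuD group (SD, n = 3). The call of this list ended after a correction for gene length (median +0.60, adjusted p = 0.0679) and for length and GC content (+0.09, adjusted p = 0.719), with quantile normalization (adjusted p = 0.0911), with fry (0.186) and with the Y-linked covariate (0.112).

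**Figure D1:**
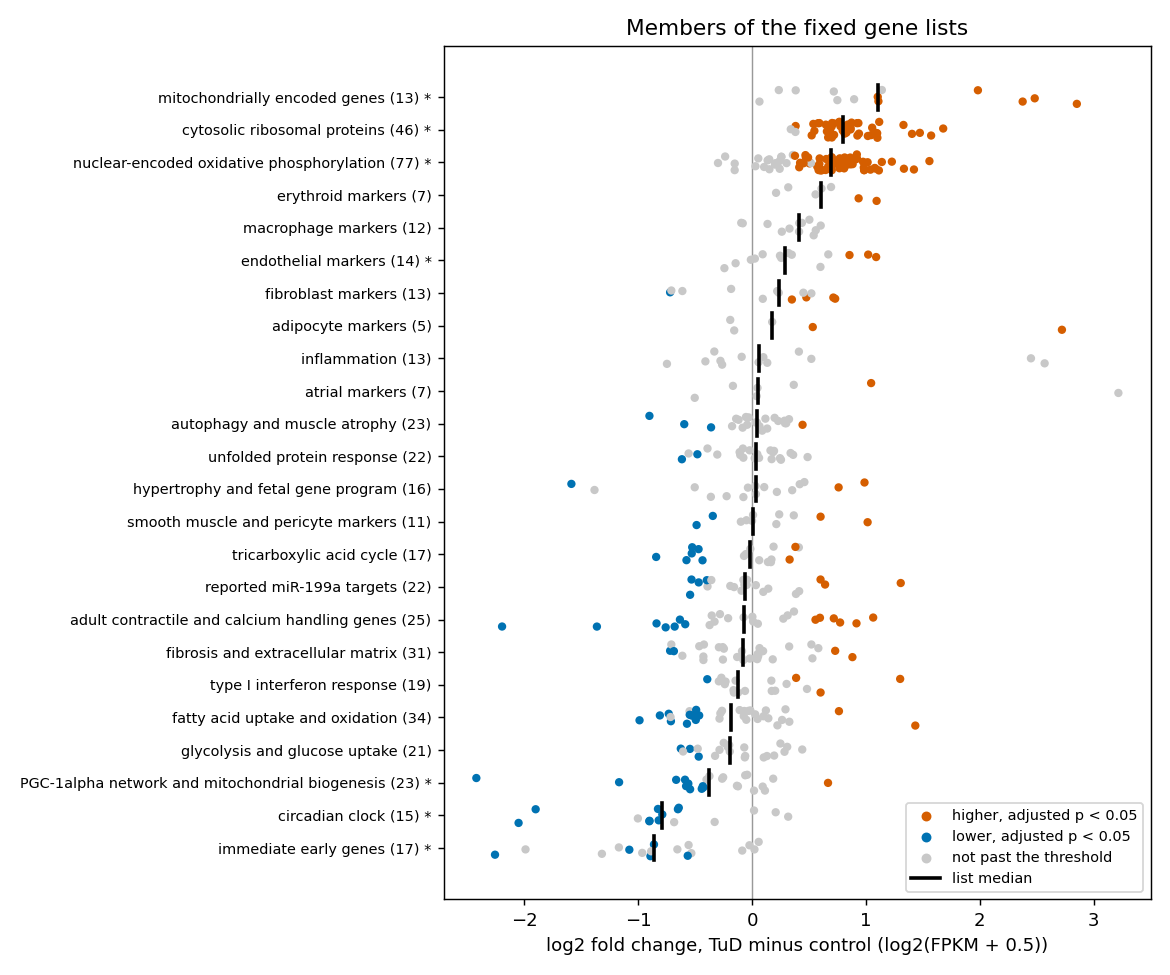
Log2 fold change (TuD minus control) of each tested member of the 24 gene lists that could be tested, with the number of members in brackets, the list median as a bar and an asterisk where the camera test with its preset correlation passed. The ribosomal protein and oxidative phosphorylation lists lie to the right of 0 (medians +0.80 and +0.69), and the circadian clock and immediate early lists to the left (-0.79 and -0.86).

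Fold changes followed gene length across the tested genes, which were not independent replicates: the correlation with log10 length was -0.386. The shortest decile of genes had a median log2 fold change of +0.49 and the longest decile one of -0.17. Within the libraries, the deviation from the mean of the 6 correlated with log10 length at 0.353, 0.285 and 0.296 in control replicates 1, 2 and 3 and at -0.243, -0.410 and -0.177 in TuD replicates 1, 2 and 3. The ribosomal protein and oxidative phosphorylation lists consisted of short genes (median lengths 1800.0 and 1718 bases), as did the mitochondrially encoded list (784 bases), and the PGC-1alpha network and circadian clock lists of longer ones (5203 and 5409 bases). After each library's trend with length was removed, a correction chosen after seeing the data, 985 of the higher genes (62.9%) and 1071 of the lower genes (71.5%) still passed. The ribosomal protein list kept a median of +0.62 (adjusted p = 2.4e-20) and the oxidative phosphorylation list one of +0.40 (adjusted p = 5.7e-14). The PGC-1alpha network list kept one of -0.26 (adjusted p = 0.0350), and one of -0.33 (adjusted p = 0.00248) after the length and GC correction.

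**Figure D2:**
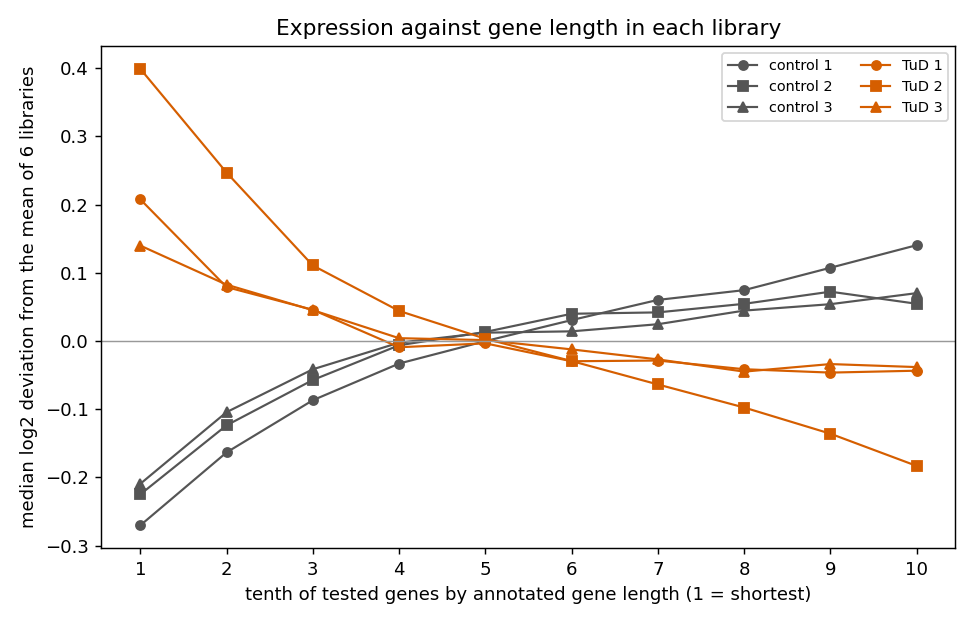
Median deviation of each library from the mean of the 6 libraries (log2 scale) in deciles of the tested genes ordered by annotated gene length, 1046 genes per decile. In the shortest decile the controls lie between -0.27 and -0.21 and the TuD libraries between +0.14 and +0.40, and in the longest decile the order is opposite.

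In the list of the PGC-1alpha network, 10 of 23 members fell, 1 rose and 12 did not pass (the same counts when adjusted over the list alone). Besides Ppara, Rxra, its dimer partner, fell from 20 ± 0.785 to 13.4 ± 0.329 normalised FPKM (-0.56 ± 0.09 SE, adjusted p = 0.00545) and Mfn2, a mitochondrial fusion protein, from 253 ± 13.6 to 160.0 ± 21.7 (-0.67, adjusted p = 0.00818; 0.0743 with the Y-linked covariate). Fis1, a mitochondrial fission protein, was the member that rose (+0.67, adjusted p = 0.00616), although not past the threshold after rescaling to TPM (adjusted p = 0.145). The list's median was -0.38 (camera adjusted p = 0.00455; adjusted p = 0.836 with an estimated correlation). The call also ended with fry (0.0789) and with the Y-linked covariate (0.0643).

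Ppargc1a itself, which encodes PGC-1alpha, a coactivator proposed elsewhere as a target of miR-199a (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726), measured 6.71 ± 1.28 normalised FPKM in the controls and 6.45 ± 1.49 in the TuD group (SD, n = 3). Its log2 fold change was -0.06 ± 0.19 (SE, adjusted p = 0.829), and the exact two-sided permutation test gave p = 0.8, where 3 samples against 3 cannot go below 0.1. The difference was smaller than the spread within either group.

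Among 34 genes of fatty acid uptake and oxidation 11 fell and 2 rose, and 21 did not pass (the same counts when adjusted over the list alone). Acsl1, which activates long-chain fatty acids, fell from 76.8 ± 4.28 to 46.1 ± 4.83 normalised FPKM (-0.73 ± 0.11 SE, adjusted p = 0.00442), and Acot2, a mitochondrial thioesterase, from 40.2 ± 1.97 to 22.9 ± 3.56 (-0.81 ± 0.13 SE, adjusted p = 0.00508). Acadvl, the very long-chain acyl-CoA dehydrogenase, fell from 283 ± 3.75 to 174 ± 30.0 (-0.71, adjusted p = 0.00819; 0.0670 with the Y-linked covariate), whereas Etfb, an electron carrier subunit, rose from 59.7 ± 4.76 to 165 ± 40.6 (+1.43, adjusted p = 0.00245). As a list they did not pass (median -0.19, camera adjusted p = 0.0558), but they did after the length correction (median -0.25, adjusted p = 0.0149) and without control replicate 1, control replicate 2 or TuD replicate 3 (adjusted p = 0.0388, 0.0326 and 0.0159). The list also passed with quantile normalization (median -0.46, adjusted p = 8.6e-05), without a filter (0.00638), with a filter at FPKM 5 (0.0423) and with the replicate block (0.0317), but not with an estimated correlation (0.836). Cpt1b, the muscle carnitine acyltransferase, stood near the filter's minimum, at 1.29 ± 0.243 and 0.780 ± 0.522 (adjusted p = 0.151; 0.0213 without TuD replicate 1 and 0.0227 after rescaling to TPM).

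Among 17 genes of the tricarboxylic acid cycle 6 fell and 2 rose (6 and 3 when adjusted over the list alone), among them Dlst (-0.58, adjusted p = 0.00790; 0.0693 with the Y-linked covariate) and citrate synthase, Cs (-0.53, adjusted p = 0.0125; 0.0510 without control replicate 3 and 0.112 with the Y-linked covariate). The list did not pass (median -0.02, adjusted p = 0.736). Of 21 genes of glycolysis and glucose uptake 3 fell and none rose, with the same counts when adjusted over the list alone (median -0.20, adjusted p = 0.340). They were Slc2a4, the insulin-responsive glucose transporter (223 ± 15.2 to 153 ± 4.46 normalised FPKM, -0.55, adjusted p = 0.00805), the hexokinase gene Hk2 (-0.63, adjusted p = 0.00831; 0.0676 with the Y-linked covariate) and the phosphofructokinase gene Pfkm (-0.47, adjusted p = 0.0188; 0.0617 without control replicate 2, 0.0798 without control replicate 3, 0.0630 without TuD replicate 1 and 0.156 with the Y-linked covariate). Both lists passed in the lower direction with quantile normalization (adjusted p = 0.00340 and 0.000865).

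Markers of hypertrophy did not move together. Ankrd1, a stress-responsive protein that binds titin (ENSMUSG00000024803, chromosome 19, 36111965 to 36119844), fell from 739 ± 59.8 to 246 ± 32.1 normalised FPKM (-1.59 ± 0.13 SE, adjusted p = 0.00159), with all 3 TuD values below the controls. The beta myosin heavy chain gene Myh7 rose from 12.1 ± 1.78 to 21.3 ± 6.48 (+0.76 ± 0.22 SE, adjusted p = 0.0359) and Xirp2, an actin-binding protein of the intercalated disc, from 7.0 ± 1.56 to 14.7 ± 4.78 (+0.99, adjusted p = 0.0236). The natriuretic peptide genes did not pass: Nppa measured 231 ± 125 and 154 ± 56.1 (adjusted p = 0.366), and Nppb 584 ± 202 and 489 ± 254 (adjusted p = 0.568). Of 16 tested members of the hypertrophy list 2 rose, 1 fell and 13 did not pass (the same counts when adjusted over the list alone), and the list did not pass (median +0.03, mean -0.05, adjusted p = 0.809). The call of Myh7 ended without any 1 of the libraries except TuD replicate 2 (adjusted p of 0.0518, 0.119 and 0.0847 without control replicates 1, 2 and 3, and 0.0980 and 0.0674 without TuD replicates 1 and 3). It ended as well after rescaling to TPM (+0.39, 0.208) and with quantile normalization (+0.73, 0.0518). That of Xirp2 ended without control replicate 2 (0.0828), TuD replicate 1 (0.0690) or TuD replicate 2 (0.0716), after the length and GC correction (+0.92, 0.0513) and with the Y-linked covariate (+0.42). Skeletal actin, Acta1, another member, stood at 401, 507 and 477 in the controls and at 398, 434 and 31.0 in TuD replicates 1, 2 and 3 (adjusted p = 0.258).

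Genes of contraction and calcium handling went both ways. Of 25 members 7 fell and 6 rose (10 and 6 when adjusted over the list alone), and the list did not pass (median -0.08, adjusted p = 0.503; -0.41 and 0.00556 with quantile normalization). Besides Slc8a1, those that fell included the gap junction gene Gja1 (38 ± 3.90 to 21 ± 1.72 normalised FPKM, -0.84 ± 0.12 SE, adjusted p = 0.00349). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 2427 ± 144 to 1577 ± 288 (-0.63, adjusted p = 0.0224), a call that ended without any 1 of the libraries except TuD replicate 3 (adjusted p = 0.0624, 0.0829, 0.0581, 0.0691 and 0.0535) and with the Y-linked covariate (0.215). Trdn, the calcium release protein triadin, rose from 9.43 ± 1.26 to 18.2 ± 2.14 (+0.92 ± 0.13 SE, adjusted p = 0.00382). The alpha myosin heavy chain gene Myh6 measured 3891 ± 337 and 4019 ± 96.5 (+0.05, adjusted p = 0.817), and its sign turned with quantile normalization (-0.52, adjusted p = 0.0220).

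**Figure D3:**
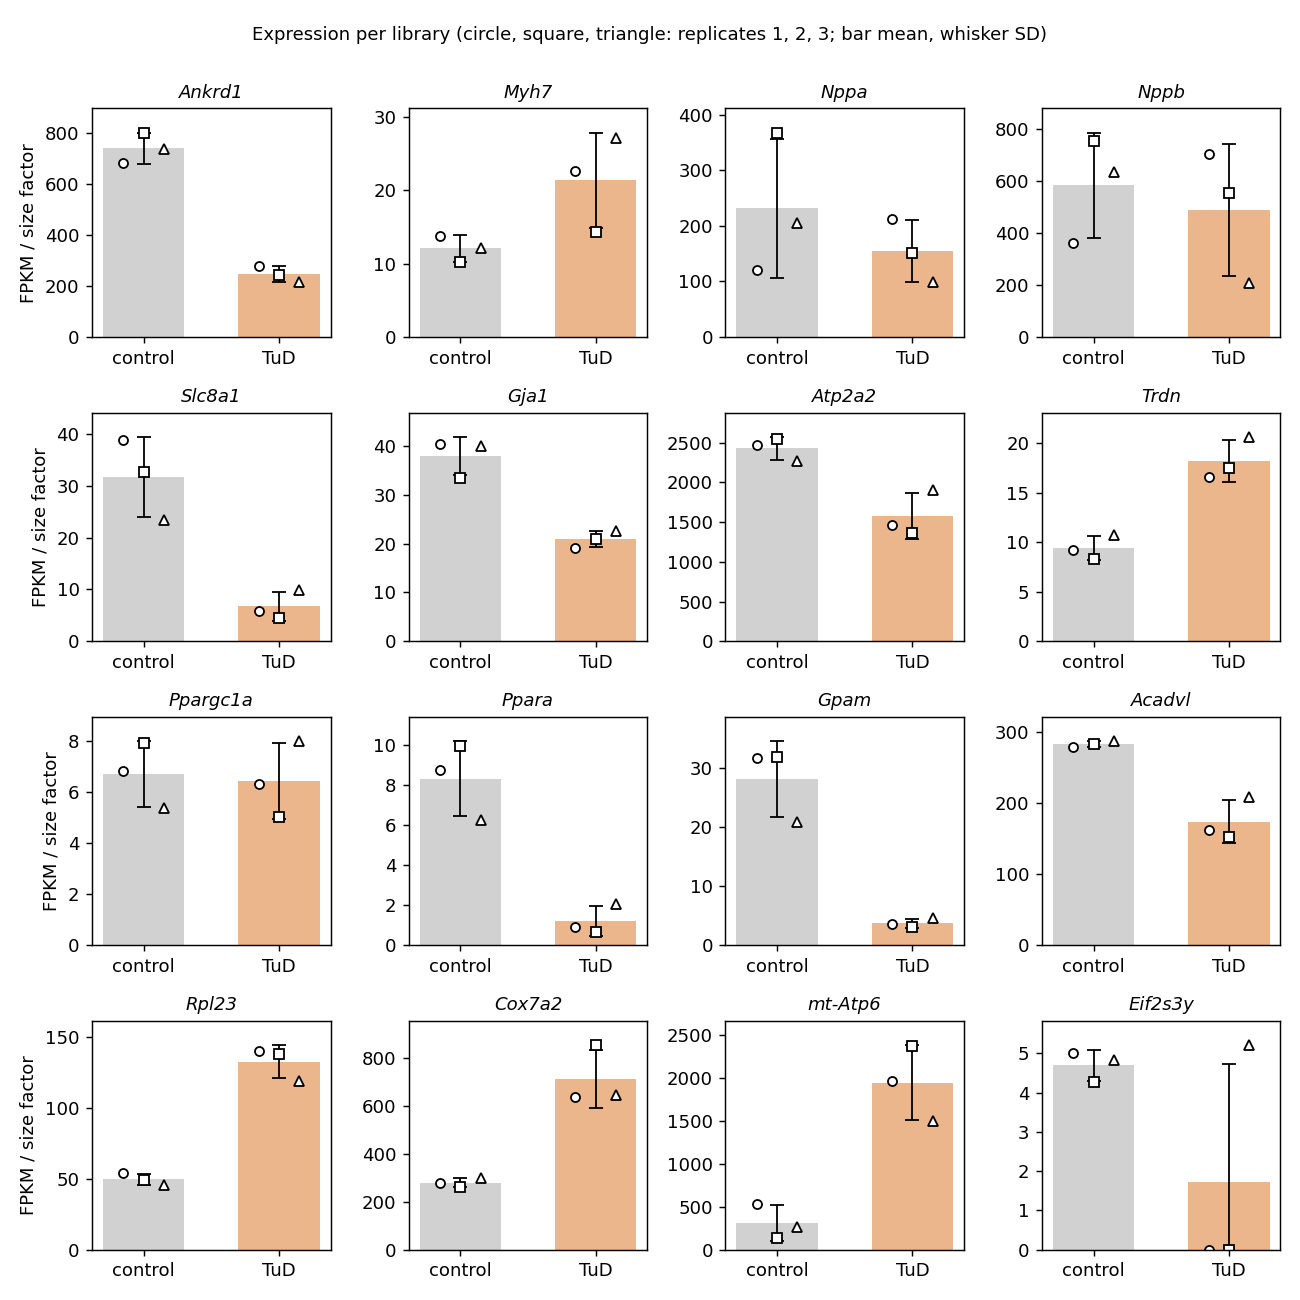
FPKM divided by the library's size factor in each library for 16 named genes, with the group mean as a bar from 0 and the SD as a whisker (n = 3 per group). All TuD values of Ankrd1, Slc8a1, Gja1, Ppara and Gpam lie below all control values, those of Rpl23, Cox7a2 and mt-Atp6 above them, and Eif2s3y is at 0 in TuD replicates 1 and 2.

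Matrix genes did not pass as a list. With the Y-linked covariate the adjusted p was 0.0120, but that estimate rests on TuD replicate 3, and the list's medians against the controls were -0.07, +0.23 and -0.35 in TuD replicates 1, 2 and 3. Among the collagens, Col1a2 fell from 14.3 ± 0.732 to 8.61 ± 2.07 normalised FPKM (-0.72 ± 0.16 SE, adjusted p = 0.0133; 0.0677 after the length correction and 0.113 with -0.44 after the length and GC correction) and Col5a1 from 6.56 ± 1.34 to 3.83 ± 0.192 (-0.69 ± 0.15 SE, adjusted p = 0.0125; 0.0952 after the length and GC correction and 0.0632 with the Y-linked covariate). Col1a1 (-0.61, adjusted p = 0.0661) and Col3a1 (-0.71, adjusted p = 0.0911) did not pass, although both did without TuD replicate 2 (adjusted p = 0.0288 and 0.0321) and after rescaling to TPM (0.00318 and 0.00678). The microfibril gene Mfap5 (+0.88, adjusted p = 0.0209) and the proteoglycan gene Lum (+0.73, adjusted p = 0.0292) rose. The call of Mfap5 ended without control replicate 1 or 3 or TuD replicate 1 or 2 (adjusted p of 0.0606 to 0.0671), and that of Lum without any 1 control (0.0572 to 0.0869). Both ended with the Y-linked covariate (0.200 and 0.258) and after rescaling to TPM (0.0618 and 0.175), and that of Lum after the length and GC correction (+0.38, 0.222). Of 31 matrix genes 2 rose and 2 fell (1 and 2 when adjusted over the list alone), with a median of -0.08 (adjusted p = 0.546).

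The circadian clock list passed in the lower direction. Of its 15 tested members 9 fell, none rose and 6 did not pass, and 10 fell when adjusted over the list alone. Ciart, a repressor within the clock, fell from 6.75 ± 4.72 to 1.06 ± 0.360 normalised FPKM (-2.05 ± 0.39 SE, adjusted p = 0.00856) and the clock output factor Tef from 31.0 ± 6.09 to 17.2 ± 2.45 (-0.83 ± 0.17 SE, adjusted p = 0.0102). Cry1 (+0.02, adjusted p = 0.952) and Nfil3 (+0.32, adjusted p = 0.626), which peak at another phase, did not pass. The list's median was -0.79 (camera adjusted p = 0.00156; adjusted p = 0.836 with an estimated correlation and 0.0583 with fry), and the hour at which each heart was taken is not in the labels.

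The list of immediate early genes, which respond to stimulation within minutes, passed in the lower direction. Of its 17 tested members 5 fell, none rose and 12 did not pass, and 7 fell when adjusted over the list alone. They included Nr4a1 (25.3 ± 11.6 to 5.06 ± 2.97 normalised FPKM, -2.26 ± 0.39 SE, adjusted p = 0.00633), the phosphatase gene Dusp1 (67.7 ± 25 to 30.9 ± 6.39, -1.08, adjusted p = 0.0151; 0.0503 without TuD replicate 2 and 0.144 with the Y-linked covariate) and the transcription factor gene Klf2 (93.6 ± 9.22 to 63.1 ± 6.63, -0.57, adjusted p = 0.0120; 0.112 with the Y-linked covariate). Control replicate 1 stood apart for members chosen after their values were seen: Fos measured 30.2 there against 3.23 and 2.93 in control replicates 2 and 3, and Egr1 38.7 against 3.70 and 4.32. The list's median was -0.86 (camera adjusted p = 0.00339; adjusted p = 0.836 with an estimated correlation, 0.161 with fry and 0.0908 with the Y-linked covariate), with a leave-one-out range of 0.000128 to 0.0142.

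Among cell type markers, the endothelial list passed in the higher direction with a median of +0.29 (camera adjusted p = 0.0480; adjusted p = 0.862 with an estimated correlation). Of its 14 members 3 rose, none fell and 11 did not pass, with the same counts when adjusted over the list alone. The 3 were the lipid carrier gene Fabp4 (67.2 ± 6.45 to 137 ± 17.3 normalised FPKM, +1.02 ± 0.13 SE, adjusted p = 0.00250), the surface marker gene Ly6c1 (122 ± 22.5 to 257 ± 30.0, +1.09 ± 0.16 SE, adjusted p = 0.00394) and the secreted factor gene Egfl7 (+0.86, adjusted p = 0.00797; 0.0629 with the Y-linked covariate). Pecam1, Cdh5, Kdr and Tie1 were among the members that did not pass. The call of the endothelial list ended without control replicate 1 (adjusted p = 0.190), TuD replicate 1 (0.0541) or TuD replicate 2 (0.121) and with the Y-linked covariate (0.590). It also ended with no size factors (0.0546), quantile normalization (0.0911), a filter at FPKM 5 (0.0783), eBayes without trend (0.0552) and fry (0.186). After rescaling to TPM the list's median was -0.10, which is +0.26 relative to all genes, and it passed in the higher direction (camera adjusted p = 0.0349). The list also passed after the length correction (median +0.32, adjusted p = 0.0149) and the length and GC correction (median +0.38, adjusted p = 0.00319).

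Fibroblast markers did not pass as a list (13 tested, 4 higher and 1 lower, 4 and 2 when adjusted over the list alone, median +0.23, adjusted p = 0.395). Tcf21 (+0.48, adjusted p = 0.0138) and Medag (+0.71, adjusted p = 0.0114) rose while Col1a2 fell, but neither passed after rescaling to TPM (adjusted p = 0.452 and 0.0701), nor did Tcf21 with the Y-linked covariate (0.0628). Dpt rose (+0.35, adjusted p = 0.0282), a call that ended without any 1 library except TuD replicate 3 (adjusted p of 0.0534 to 0.108) and after the length correction (+0.12, 0.303), quantile normalization (+0.19, 0.0974), the replicate block (0.0543) and the Y-linked covariate (0.146). After rescaling to TPM it stood at -0.04, where the median of all tested genes was -0.36. Smooth muscle and pericyte markers did not pass either (11 tested, 2 higher and 2 lower, 3 and 2 when adjusted over the list alone, median +0.01, adjusted p = 0.736), with Rgs5, a pericyte marker, rising from 30.9 ± 5.0 to 63.3 ± 13.6 normalised FPKM (+1.01, adjusted p = 0.00609; 0.0574 with the Y-linked covariate). Adipocyte markers held 5 tested members, of which Cfd and Scd1 rose, also when adjusted over the list alone (median +0.18, adjusted p = 0.361). The call of Scd1 ended after rescaling to TPM (+0.20, 0.283), and the list passed without a filter (0.0428) and with fry (0.0402).

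Macrophage and erythroid markers differed more within the TuD group than between the groups. Of 12 macrophage markers none passed, over all genes or over the list alone (median +0.41, camera adjusted p = 0.0994). Of 7 erythroid markers the globin genes Hba-a1 and Hba-a2 rose, also when adjusted over the list alone (median +0.61, adjusted p = 0.0908). Against the mean of the controls, the macrophage median was -0.07, +0.38 and +0.91 in TuD replicates 1, 2 and 3 and the erythroid median -0.15, +0.77 and +1.17. Without TuD replicate 1 both lists passed (adjusted p = 0.000864 for each), and the erythroid list also passed without control replicate 2 (0.0326). The macrophage and erythroid lists passed as well after rescaling to TPM (adjusted p = 0.0349 and 0.0125) and without a filter (0.0104 and 0.0314). With the Y-linked covariate (4.3e-06 and 0.00194) the estimate rests on TuD replicate 3, the highest library for both. After the length correction the medians were +0.21 and +0.22 (0.271 and 0.319), and with an estimated correlation the adjusted p was 0.862 for both. The call of Hba-a1 ended without any 1 library except TuD replicate 1 (adjusted p of 0.0745 to 0.141), and that of Hba-a2 without control replicate 1 or 3 or TuD replicate 2 (0.0580 to 0.0677). The Y-linked covariate also ended the call of Hba-a2, although its estimate grew to +1.36. The length correction ended both (Hba-a1 +0.50, 0.255; Hba-a2 +0.61, 0.122), as did rescaling to TPM (0.188 and 0.0731) and the length and GC correction (0.203 and 0.0948). That of Hba-a1 also ended with quantile normalization (+0.49, 0.256), no size factors (0.0514), eBayes without trend (0.0512), robust eBayes (0.0590) and the replicate block (0.0519).

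TuD replicate 3 stood apart for other markers as well. Igkc, an immunoglobulin light chain gene chosen after its values were seen, measured 398 normalised FPKM there against 3.09 to 5.99 in the other 5 libraries. The neutrophil genes S100a8 (58.5 against 0.146 to 2.06) and S100a9 (89.9 against 0.504 to 2.94) and the atrial light chain gene Myl7 (90.8 against 0.178 to 1.44) were also highest in that library. The labels do not describe the dissection. Neither a difference in the tissue taken nor a wrong label was tested for this library, on which the estimates with the Y-linked covariate rest. The inflammation list did not pass and had no member past the threshold, over all genes or over the list alone (13 tested, median +0.06, adjusted p = 0.899). Of 7 atrial markers Dkk3 rose (adjusted p = 0.0463; 0.0953 to 0.133 without control replicate 1 or 3 or TuD replicate 2 or 3 and 0.0811 with the Y-linked covariate) and none fell. Its call also ended after rescaling to TPM (0.103), quantile normalization (0.0533), the length correction (0.0540), the length and GC correction (0.0531) and robust eBayes (0.0575). None passed when adjusted over the list alone, and the list did not pass (median +0.05, adjusted p = 0.630).

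Stress pathways showed no common direction. In the unfolded protein response list 2 of 22 members fell and none rose, also when adjusted over the list alone (median +0.03, mean -0.01, adjusted p = 0.963). In the autophagy and atrophy list 3 of 23 fell and 1 rose with the same counts when adjusted over the list alone (median +0.04, adjusted p = 0.899). In the type I interferon list 3 of 19 rose and 1 fell (2 and 0 when adjusted over the list alone; median -0.12, mean +0.07, adjusted p = 0.899). The kinase gene Ulk1, which starts autophagy, fell from 20.9 ± 2.79 to 10.9 ± 0.798 normalised FPKM (-0.90 ± 0.12 SE, adjusted p = 0.00348). Ifi27, an interferon-induced gene, rose from 22.1 ± 0.569 to 57.5 ± 20.4 (+1.3 ± 0.22 SE, adjusted p = 0.00616).

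Reported targets of miR-199a, listed from background knowledge, did not move as a group. Of 22 tested members 3 rose and 4 fell, with the same counts when adjusted over the list alone, and the list did not pass (median -0.06, mean +0.01, adjusted p = 0.738). Cav2, a caveolae component, rose from 3.26 ± 0.945 to 8.63 ± 0.818 normalised FPKM (+1.31 ± 0.18 SE, adjusted p = 0.00336), and the kinase gene Mtor fell from 7.61 ± 0.575 to 5.12 ± 0.514 (-0.53, adjusted p = 0.0124; 0.0515 without control replicate 2, 0.0892 with -0.27 after the length and GC correction, 0.0776 with the replicate block and length correction and 0.105 with the Y-linked covariate). Of the genes that host the microRNA, Dnm2 measured 20.4 ± 0.865 and 19.0 ± 1.26 (-0.10, adjusted p = 0.460; -0.49 and 0.0173 after rescaling to TPM), and Dnm3os, at 0.0132 and 0.0578 with 6 and 21 reads, was too low to test. Mature microRNAs were not measured.

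Genes whose annotated 3' UTR holds a site for the seed of miR-199a-5p lay slightly lower in the TuD group. Targets released from the microRNA by a decoy would lie higher, so this shift has the opposite sign. The 1442 tested genes with such a site had a median log2 fold change of -0.10 against +0.01 for 7555 genes with a searched 3' UTR and neither site (camera adjusted p = 0.00941; 0.382 with an estimated correlation). Of the genes with a site 125 rose (8.67%) and 298 fell (20.7%), against 14.6% and 13.8% of those without. The 746 genes with a site for miR-199a-3p had a median of -0.05 (adjusted p = 0.0882). Genes with a site were longer (median 5542 bases for miR-199a-5p and 3814 without a site), and the miR-199a-5p difference of -0.11 shrank to -0.03 against genes matched on 3' UTR length and expression (adjusted p = 0.607) and to -0.04 after the length correction (0.516).

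**Figure D4:**
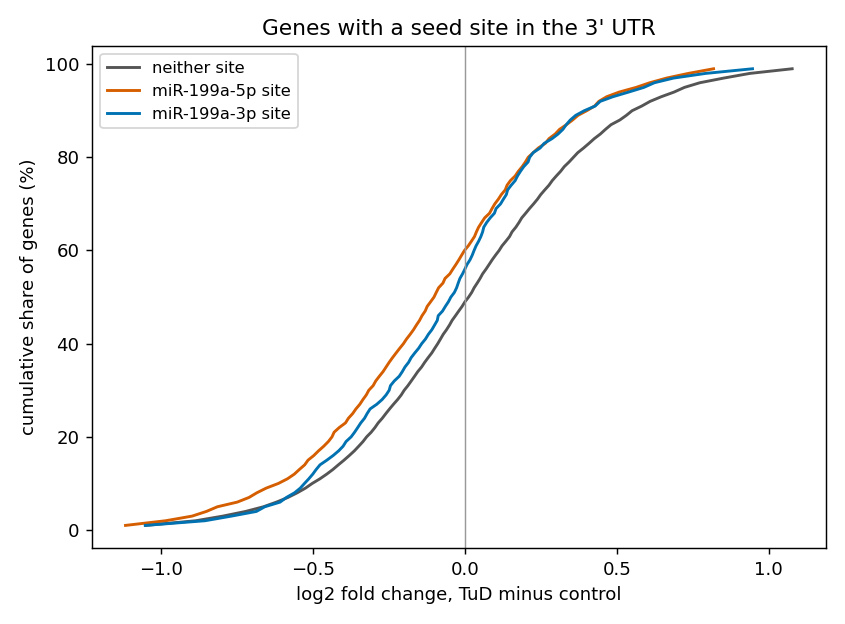
Cumulative share of tested genes (percent) by log2 fold change (TuD minus control) for genes with a seed site of miR-199a-5p (1442 genes), with one of miR-199a-3p (746 genes) and with neither (7555 genes). The medians are -0.10, -0.05 and +0.01. The curve of genes with a miR-199a-5p site lies to the left of the curve without a site, and that of genes with a miR-199a-3p site crosses it at low log2 fold changes.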

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

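The corrections for gene length and GC content, the restriction to protein-coding genes and the Y-linked covariate were chosen after the data were seen, and the other alternatives before. For 129 named genes other than Ppargc1a, 2795 values under the alternatives stayed on the same side of the threshold in 2424 cases, fell short of it in 300, passed it in 68 and reversed in 3. In 23 of the 2424 cases the sign changed without a call. The 3 were Dpt (-0.0366 after rescaling to TPM, where the median of all genes was -0.36), Myh6 (-0.52 with quantile normalization) and Ddx3y (+0.92 with the Y-linked covariate). That covariate was defined from Ddx3y and the other Y-linked genes, so the value of Ddx3y there is no independent result. Of 569 values for the 24 lists, 518 stayed on the same side of the threshold, 26 fell short and 25 passed. In 37 of the 518 cases the direction changed without a call. Ppargc1a stayed short of the threshold under every alternative, between -0.22 and +0.10 when 1 library was left out. Apart from fewer samples, fewer or more genes tested and the share of calls that a threshold removes, the cause was not tested.

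Genes higher and genes lower in the TuD group numbered 438 and 4202 after rescaling to TPM, 1010 and 956 without a filter, 228 and 153 at a log2 change of at least 1, and 651 and 529 with the Y-linked covariate. Genes higher numbered 954 after the length and GC correction and 957 with the replicate block and length correction. Leaving out 1 library gave 878 to 1638 higher and 718 to 1620 lower genes, with the lowest values without control replicate 2 and the highest without TuD replicate 3. Lists passing numbered 2 higher and 7 lower with quantile normalization, 7 higher without a filter, 0 and 0 with an estimated correlation and 0 lower with fry, and 3 to 5 higher and 3 to 4 lower when 1 library was left out.

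The difference for miR-199a-5p sites lost its call without a filter (-0.0330), after the length correction (-0.0362), the length and GC correction (-0.0752) or the replicate block and length correction (-0.0362), with the Y-linked covariate (-0.0737), with 8mer sites only (-0.0672), against matched genes (-0.0339, and -0.0310 with the length correction as well), and with an estimated correlation (-0.11, adjusted p = 0.382). Its adjusted p over all alternatives ran from 0.000137 to 0.607, and with 1 library left out the difference was -0.14 to -0.0814. For miR-199a-3p the test passed with a filter at FPKM 5 (-0.10), with 6mer sites (-0.14) and without TuD replicate 3 (-0.0858), in a leave-one-out range of -0.0858 to -0.0182.

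The labels do not say whether replicate numbers pair the samples. Deviations of control and TuD libraries with the same number correlated across genes at 0.0637, 0.0882 and -0.0554, and those with different numbers at -0.161 to 0.0934. These values show no pairing but cannot exclude one. A block for the number gave 1462 higher and 1199 lower genes. In the simulated data, with the same dispersion for every gene, 4.08% of the smallest simulated changes and 91.7% of the 2-fold ones were recovered.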

Other observations

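The tests of gene length on the circadian clock list and of the sex of the animals were chosen after the results were seen. The corrections for length and GC content were also added after the data were seen, but the bounds for the 3 lists of short genes were set before their corrected values were known.

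Beyond the fixed lists, protein-coding genes were grouped by the stem of their symbols, which gave 156 families of at least 8 tested members. The families named here were chosen after their values were seen. Of solute carriers (Slc), the membrane transporters, with 155 members, 49 fell and 6 rose (median -0.22, camera adjusted p = 0.00189; adjusted p = 0.842 with an estimated correlation), and the test still passed after the length correction (median -0.17, adjusted p = 0.0337). Proteasome beta subunits (Psmb) rose in 6 of 10 cases and fell in none (median +0.52, adjusted p = 0.0136; 0.155 after the length correction; 0.842 with an estimated correlation). Mitochondrial ribosomal proteins of the large subunit (Mrpl) rose in 17 of 48 cases and fell in 2 (median +0.30, adjusted p = 0.00366; 0.842 with an estimated correlation), but their median was -0.01 after the length correction (adjusted p = 0.532) and turned to -0.08 after rescaling to TPM, which is +0.27 relative to all genes. Of 18 collagens (Col) 5 fell and none rose (median -0.43, adjusted p = 0.0241; 0.280 after the length correction; 0.842 with an estimated correlation). Translation factors did not pass as families: of 50 Eif genes 13 rose and 3 fell (adjusted p = 0.281), and of 12 Eef genes 4 rose and 1 fell (adjusted p = 0.350).

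The lists with too few tested members gave values only. Of the cell cycle list 4 of 20 members could be tested. Pcna rose from 11 to 14.8 normalised FPKM (+0.40, adjusted p = 0.0421), a call that ended without any 1 library except TuD replicate 1 (adjusted p of 0.0805 to 0.132). It ended as well after rescaling to TPM (+0.02, 0.911), the length correction (+0.30, 0.0924), the length and GC correction (+0.20, 0.204), the replicate block (0.0613; 0.125 with the length correction) and the Y-linked covariate (0.0698). The same held with no size factors (0.0503), eBayes without trend (0.0516) and no filter (0.0869). Mki67, the proliferation marker, measured 0.207 normalised FPKM in the controls and 0.108 in the TuD group. Of the lymphocyte list 2 of 16 were tested, among them Ighm (2.63 and 4.66, +0.72, adjusted p = 0.0277). Mki67 and Ighm were chosen after their values were seen. Of the skeletal muscle list 3 of 14 were tested, and Tnni2, the fast troponin I gene, rose from 0.407 to 1.57 (adjusted p = 0.00557; 0.0552 with the Y-linked covariate). The mesothelial and valve list (2 of 12 tested) and the neural list (2 of 12) stayed at or below group means of 1.94 and 1.37. The lung list (0 of 10) stayed at or below 1.22, a value that came from Scgb1a1 in control replicate 3 (3.65, and 0 in the other 5 libraries). The sex marker list held 2 of 5 and the miR-199a host list 1 of 7 tested genes.

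Reads in genes of the rRNA biotypes, mitochondrial rRNA included, made up 0.355, 0.411 and 0.390% of the reads in control replicates 1, 2 and 3 and 0.904, 1.09 and 0.709% in TuD replicates 1, 2 and 3. Against the mean of the controls, the ribosomal protein median was +0.66, +1.03 and +0.66 and the oxidative phosphorylation median +0.62, +0.89 and +0.55 in TuD replicates 1, 2 and 3.

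The lists of ribosomal proteins, oxidative phosphorylation and, with 6 of 13 members passing, the mitochondrial genome passed in the higher direction, and these are short genes in libraries that differ in their trend with length. Removing each library's trend left the ribosomal protein median at 0.617 (0.80 before) and the oxidative phosphorylation median at 0.397 (0.69 before), both past the threshold. Removing length and GC trends together left 0.678 and 0.375. These values argue against a trend with annotated gene length, alone or with GC content, as the whole of both differences. A bias with the length of the transcripts actually expressed was not tested, since only annotated lengths were used. The mitochondrially encoded list went from +1.10 (quartiles 0.72 and 1.98) to 0.605 after the length correction (quartiles 0.25 and 1.51) and to 0.091 after both (quartiles -0.05 and 1.09); its calls ended with a smaller median and a spread that stayed wide, and bias with length and GC is a candidate explanation for that list. The model with the Y-linked covariate rests on TuD replicate 3 and excludes no explanation for the other 2 lists. What remains of these 2 lists may follow the treatment, the sex of the animals or the quality of RNA and libraries, and quality was not tested.

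The clock list passed in the lower direction, and a different hour of collection is a candidate explanation. If the hearts had been taken at another hour, genes of the activating phase would move opposite to those of the output phase. The 2 tested genes of the activating phase, Cry1 and Nfil3, had a median of +0.17 and the 10 of the output phase one of -0.82, with 9 of them below 0. The difference of 0.991 has the sign such a shift needs, although it rests on 2 genes that did not pass by themselves. Among activators too low to test, Arntl measured 0.377 and 1.13 normalised FPKM and Clock 0.588 and 1.06. After the length correction the clock list kept a median of -0.66 (adjusted p = 0.00263), which argues against a trend with annotated gene length as the whole cause. An effect of the treatment on the clock stays open.

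The number of genes that differ between the groups may include genes that differ by sex, since 2 of the 3 TuD libraries lack Y-linked transcripts and no control does. Genes called from those 2 libraries against 2 controls kept their sign in TuD replicate 3 minus the held-out control in 94.1% (2472 of 2626), 92.3% (2045 of 2215) and 92.9% (2063 of 2220) of cases. Since 1 library carries that check, sex and treatment cannot be told apart for the group counts, and the treatment stays among the open explanations. With Y-linked transcripts as a covariate, 531 of the higher genes and 433 of the lower genes passed again in the same direction. The real split of the 6 samples gave 3063 genes and the highest of the other splits 1, so 1 of 10 splits gave as many, and with 10 splits a share under 0.05 cannot be reached.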
